A study of Mus musculus with 23 samples.

How the data were processed

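RNA was measured by bulk sequencing in 23 mouse libraries, 12 from sorted GFP-negative and 11 from sorted GFP-positive cells. Per the labels' protocols, RNA was purified with TRIzol and a PureLink column kit, and poly(A)-selected libraries were made with the NEBNext Ultra II Directional kit. The protocol text speaks of organoids as the RNA source, whereas the design text speaks of digested primary tumours, and this difference could not be settled from the labels. The series title carries the letters HFD, but no label gives a diet for any library, so diet entered no comparison.

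The table holds expected counts (estimated counts of reads per gene) as deposited by the authors, made with Salmon per the submitters' processing notes and already whole numbers, so no rounding was needed. The notes name Salmon 1.3.0 and the mm10 mouse genome; the transcript annotation and the Salmon options are not given in the sources used here. Salmon divides reads that match several transcripts in proportion to its model, so counts of near-identical genes (paralogues, pseudogenes, the Amy2a copies, the ribosomal repeats) are uncertain estimates. Of the 54354 gene identifiers in the table, 51528 (94.8%) were in GENCODE release M21, the mm10 annotation used for gene symbols and coordinates; 1243 genes had no symbol. All sample columns matched a library name in the labels.

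Groups came from the GFP status in the labels. The identifier at the start of each library name was read as a possible common source of a GFP-positive and a GFP-negative library. 10 identifiers had both populations, with 8045, 8050 and the joined name 8045-8050 treated as 1 identifier and both GFP-positive libraries of 61-1 averaged within that identifier. The library numbers fell into 2 runs, called library set 1 (6 GFP-negative and 5 GFP-positive libraries) and library set 2 (6 and 6), which was read as a possible batch. The names of GFP-negative 9, GFP-positive 7 and GFP-positive 8 also end in a suffix -2 whose meaning the labels do not give, and which was not used. It sets GFP-positive 7 apart from GFP-positive 2 and GFP-negative 8, the other libraries of identifier 61-1, so the labels leave open whether the libraries of 61-1 came from 1 tumour. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. The replicate numbers in the titles shared an identifier in 2 of 11 cases. No pair of libraries of a group matched within sampling noise in a chi-square test of their counts, so none was counted as a repeat. Reads without molecular identifiers are not independent, so repeats could fail this test too, and it cannot exclude them. Each library entered the main fit as its own unit.

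Total counts ran from 25458 to 4238877 per library, and 4 libraries held fewer than 100000. The interval of a fitted fold change is taken from its standard error and reflects the spread between libraries. Floors cover counting error alone, since reads without molecular identifiers are not independent molecules; the floor for a count of 0 was set at 3 counts per library.

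The comparison of GFP-positive with GFP-negative libraries used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, a robust quasi-likelihood fit with no covariate, and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are GFP-positive minus GFP-negative, SE is their standard error, and n is the number of libraries. CPM values of genes and of sums of genes are counts divided by the library total and rescaled to a common sum, without TMM factors. The same test was fitted within each library set, and an interaction of group with library set was fitted over all libraries. Single measures were compared by two-sided permutation tests with 100000 resamples, and differences within identifiers by exact two-sided sign-flip tests. Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, over the 23 of 35 lists with at least 5 tested members. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance. A list score is the mean log2 CPM of its tested members, here with TMM factors and a prior count of 2. 573 of the 575 genes in the lists were in the table.

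The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names (a) Basp1; (b) up to 10 genes with the largest and 10 with the smallest log2 fold change among those past the threshold, with a mean log2 CPM of at least 3, a symbol, and the same sign in at least 8 of 10 identifiers or the same share; (c) for each list the members past the threshold with the smallest p, at most 3, or else its most expressed member; (d) Lgr5, Clu, Anxa1, Ly6a, Emp1, Mki67, Krt20, Epcam, Ptprc, Col1a1 and Pecam1; and (e) genes with the largest shares of the counts where 1 gene took over 5% of a library. Parts (a) to (d) were written for all 23 libraries. Part (b) was applied to library set 2 in the same way; any other gene named was chosen after its values were seen.

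Alternatives fixed beforehand were blocks by identifier, by title number and as a random effect in limma voom, DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, a filter of at least 10 counts in 11 libraries, library set as a covariate, each library set alone, both GFP-positive libraries of 61-1 summed, leaving out joined identifiers, a fold of at least 1.5 as the null, and leaving out each library and each identifier in turn. Alternatives added after the data were seen used libraries of at least 100000 counts, thinned or not, left out GFP-positive 3, weighted libraries by quality, took macrophage and fibroblast scores as covariates, estimated the correlation of 3 lists in single alternatives, or left out GFP-positive 3 or identifier 7789-7795 within library set 1, identifier 8045-8050 for Basp1, and GFP-positive 2 from score differences between library sets. Pseudocount alternatives were not run, because the table holds counts. The name of 1 gene called in an alternative is not reported here.

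The count test was tested on simulated data with 200 genes changed, drawn from the fitted means, dispersions and library sizes. With 6621 genes simulated for all libraries, 51.5% of genes changed by 2-fold, 94.0% by 4-fold and 98.5% by 8-fold were called, and 5 of 6347 unchanged genes were called. For library set 1 (5256 genes simulated) the shares were 10.8%, 75.8% and 97.0%, with 3 of 4875 unchanged genes called. For library set 2 (6952 genes simulated) they were 9.23%, 79.7% and 98.4%, with 6 of 6497. Genes were simulated independently of each other, so the simulation does not bear on the preset correlation of camera. No simulated library was made to stand apart from its group, so the shares may be too high for genes that single real libraries move. They may also be too high because many true changes ease the Benjamini-Hochberg threshold. The simulation had 200 changed genes, some by 8-fold. Figures were drawn with matplotlib 3.10.9.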

Results

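Basp1 encodes a membrane-associated signalling protein, and the tumours studied carried a Basp1 reporter with green fluorescent protein and the diphtheria toxin receptor. The reporter was carried by AKP organoids, cultured mouse intestinal tumour epithelium marked with tdTomato, that had been injected into the colon of mice. Primary tumours were digested and sorted by GFP, giving 12 GFP-negative and 11 GFP-positive libraries. The series title names revival stemness, a regenerative epithelial state marked by Clu and Anxa1, together with ceramides and metastasis, so the comparison asks how Basp1-reporter-positive tumour cells differ from reporter-negative cells of the same kind of tumour. Depth was low and uneven: the median total count was 144334 in GFP-negative libraries (25458 to 2304316, n = 12) and 1418140 in GFP-positive libraries (37125 to 4238877, n = 11). The groups differed 4.53-fold in geometric mean depth (permutation p = 0.0162, Benjamini-Hochberg adjusted p = 0.0809 over 5 quality measures). GFP-negative 4, GFP-negative 5, GFP-negative 12 and GFP-positive 4 held 57728, 25458, 69580 and 37125 counts. The mitochondrial ribosomal genes mt-Rnr2 and mt-Rnr1 took 20.8% and 11.3% of the counts in GFP-negative 4, against medians of 2.58% and 0.554% over the libraries, and Rn18s-rs5, a nuclear ribosomal repeat, took 5.29% in GFP-positive 10. The highest shares of mt-Nd4, mt-Co3 and Malat1 were 2.12% (GFP-negative 4), 2.64% (GFP-negative 5) and 4.72% (GFP-negative 11). The share of mitochondrial ribosomal RNA did not separate the groups (permutation p = 0.599).

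Basp1 itself (ENSMUSG00000045763, chromosome 15, 25363277 to 25413764 on mm10, minus strand) was measured first, because it checks the sort labels. Its level was 33.4 ± 27.0 CPM in GFP-negative libraries (SD, n = 12) and 57.8 ± 32.9 CPM in GFP-positive libraries (SD, n = 11). The log2 fold change was 0.63 (SE 0.38, 95% interval -0.11 to 1.38), which did not pass the threshold (edgeR quasi-likelihood test, p = 0.103, Benjamini-Hochberg adjusted p = 0.997). Basp1 was higher in the GFP-positive population of 7 of 10 identifiers (mean log2 difference 1.03, exact sign-flip p = 0.127). The largest difference, 6.76 in identifier 8045-8050, set 4 counts in GFP-positive 4 against 0 in both GFP-negative libraries; without it Basp1 was higher in 6 of 9 identifiers, with a mean of 0.39 ± 0.95 (SD, n = 9, exact sign-flip p = 0.254). A permutation test of log2(CPM + 1) over libraries gave p = 0.0703. In library set 1 the means were 35.0 ± 34.3 and 68.3 ± 26.3 CPM (SD, n = 6 and 5), and in library set 2 they were 31.8 ± 20.7 and 49.0 ± 37.6 CPM (SD, n = 6 and 6). No Basp1 count was seen in GFP-negative 4 and GFP-negative 5, where 3 counts would stand for 52.0 and 118 CPM, so absence could not be told from low depth there. The Basp1 transcript therefore overlapped widely between the sorted populations.

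**Figure D1:**
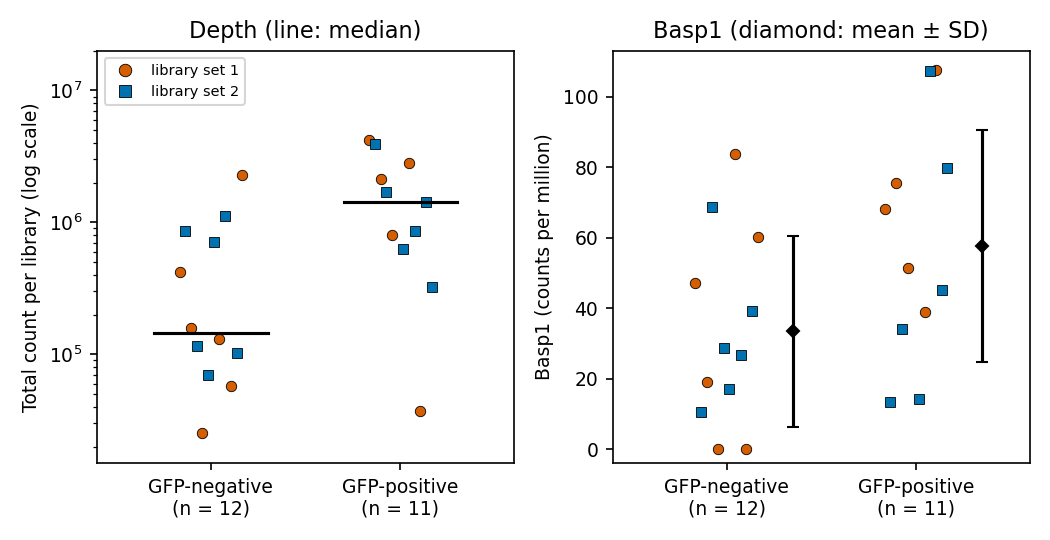
Left, total count of each library on a log scale, with the group median as a line; right, Basp1 in CPM per library, with the group mean ± SD as a diamond. Median depth was 144334 in GFP-negative (n = 12) and 1418140 in GFP-positive libraries (n = 11), and Basp1 averaged 33.4 and 57.8 CPM with overlapping libraries.

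Across all 23 libraries, 1 of 6621 tested genes differed between the populations. Fbln1 (ENSMUSG00000006369, chromosome 15, 85205949 to 85286535, plus strand), which encodes the extracellular matrix glycoprotein fibulin-1, fell by 3.17 on the log2 scale in GFP-positive cells (SE 0.54, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0119). Its level was 56.9 ± 62.6 CPM in GFP-negative (SD, n = 12) and 5.45 ± 5.48 CPM in GFP-positive libraries (SD, n = 11), and it was lower in the GFP-positive population of 10 of 10 identifiers. No gene was called higher by edgeR, with 181 genes higher and 147 lower at an unadjusted p under 0.05, 328 in all. Evenly spread p-values would give 331. Other splits of the libraries into groups of these sizes had a median of 217, and 13 of 100 splits, the real split included, had 328 or more. DESeq2 called 61 genes, 2 higher and 59 lower. The edgeR count rested on single libraries. Without GFP-positive 3, which carried macrophage transcripts, 16 genes were called, and without GFP-positive 1 there were 3. It was 0 without GFP-negative 1, 2, 5, 6, 7, 8, 9, 10, 11 or 12. Fbln1 fell below the expression filter in those 10 fits and in the fit without GFP-positive 1, and passed in the 12 fits that tested it. Leaving out whole identifiers gave 27 genes without 7789-7795 and 0 without 40-1, 61-1, 7421 or 7914, and Fbln1 missed the threshold without 7421 (adjusted p = 0.0720) and without 7914 (adjusted p = 0.116).

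Genes of the revival and fetal-like stem list showed small differences that did not pass the threshold. Clu, which encodes clusterin and marks revival stem cells, averaged 1048 ± 654 CPM in GFP-negative (SD, n = 12) and 1771 ± 899 CPM in GFP-positive libraries (SD, n = 11), a log2 fold change of 0.69 (SE 0.33, edgeR unadjusted p = 0.0483, adjusted p = 0.996). Clu passed the threshold without GFP-positive 3 under a block by identifier (0.80, edgeR adjusted p = 0.0195), an alternative chosen after the result was seen, but not when libraries under 100000 counts were left out too (0.59, adjusted p = 0.202) nor with a block in library set 2 (0.49, adjusted p = 0.311). Anxa1 had 0.35 (SE 0.15, unadjusted p = 0.0217, adjusted p = 0.951) and was higher in 8 of 10 identifiers. S100a6, Ly6a and Emp1, of the same list, had 0.16 (SE 0.15), 0.13 (SE 0.16) and 0.05 (SE 0.29). Of 21 tested members, 16 had a positive fold change, the median was 0.16, and 0 were called over all genes or adjusted over the list alone (camera adjusted p = 0.562, and 0.793 with an estimated correlation). The list score differed by 0.20 ± 0.33 within identifiers (SD, n = 10, exact sign-flip p = 0.0703, adjusted p = 0.314). Its largest difference, 0.96, was that of 8045-8050, whose libraries held 25458 to 57728 counts. The others ran from -0.21 to 0.50. Lgr5 (ENSMUSG00000020140), the marker of crypt base stem cells, lay below the expression filter with 90 counts over the GFP-negative and 231 over the GFP-positive libraries, or 14.4 ± 17.8 and 18.9 ± 16.8 CPM (SD, n = 12 and 11, permutation p = 0.147). The crypt base stem list had a median of -0.09 over 9 members (adjusted p = 0.436), with its most expressed member Slc12a2 at 0.34 (SE 0.34). WNT targets had a median of 0.00 over 10 members (adjusted p = 0.664), where the test leaned downwards, with Ccnd1 at 0.28 (SE 0.20). YAP and TAZ targets had a median of -0.14 over 12 members (adjusted p = 0.562), with F3 at 0.53 (SE 0.37), and adjusted over the list alone 1 member was called lower.

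Among lists of tumour cell state, G2/M and hypoxia genes leaned lower in GFP-positive cells, with scores lower in 7 and 8 of 10 identifiers, whereas cholesterol genes passed camera as lower with a score lower in 4 of 10 identifiers. Hypoxia differences in 40-1, 5780, 7789-7795 and 7968 were only -0.055, -0.034, -0.003 and -0.022. The largest hypoxia and G2/M differences, -1.40 and -1.41, were those of 8045-8050, whose libraries held 25458 to 57728 counts. Of the 14 tested G2/M genes, 13 had a negative fold change, with a median of -0.67, and 2 were called lower adjusted over the list alone. The proliferation marker Mki67 had -0.76 (SE 0.41, edgeR adjusted p = 0.996) and Top2a, a topoisomerase of dividing cells, had -0.27 (SE 0.23). The list passed camera with its preset correlation (adjusted p = 5.83e-09), and not with an estimated correlation (adjusted p = 0.0535). Hypoxia and glycolysis genes had a median of -0.39, with 12 of 16 lower and 1 called lower adjusted over the list alone, and Ldha, lactate dehydrogenase A, had -0.47 (SE 0.18, adjusted p = 0.939). Camera gave an adjusted p of 5.15e-06 for this list, and 0.0669 with an estimated correlation. Cholesterol synthesis genes had a median of -0.08, with 12 of 18 lower and 1 called lower adjusted over the list alone. Fdps, farnesyl diphosphate synthase, had -0.77 (SE 0.22, unadjusted p = 0.00117, adjusted p = 0.594), and the list gave a camera adjusted p of 0.00411, and 0.446 with an estimated correlation. Fry called none of the lists (smallest adjusted p 0.240). Exact sign-flip tests of list scores over identifiers called none either (smallest adjusted p 0.290). With 10 identifiers their smallest possible exact sign-flip p is 0.00195, so over 33 lists no single list could pass on its own. None of the genes in these lists passed the threshold over all genes.

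Sphingolipid genes, which include the enzymes that make and break down ceramides, did not differ detectably. Their median was 0.13 over 25 members, 17 of them positive (camera adjusted p = 0.602), with the acid ceramidase gene Asah1 at 0.22 (SE 0.21). The score of this list was higher in 8 of 10 identifiers, by 0.22 ± 0.32 (SD, n = 10, exact sign-flip p = 0.0488, adjusted p = 0.314). Genes of PPAR signalling and fatty acid oxidation had a median of 0.16 over 13 members (adjusted p = 0.664), with Ucp2 at -0.39 (SE 0.21). Epithelial identity genes had 13 of 14 members positive, a median of 0.27 and an adjusted p of 0.163; of them Epcam, an epithelial adhesion protein, had 0.55 (SE 0.24, adjusted p = 0.992) and Krt19 had -0.07 (SE 0.17). Basement membrane and invasion genes had a median of 0.36 over 18 members (adjusted p = 0.415), with Cd44 at 0.44 (SE 0.24).

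The lists of differentiation, S phase, p53, interferon, MHC class I, NF-kB, TGF-beta, unfolded protein response and dissociation genes did not pass the camera threshold, and none of their members was called by edgeR adjusted over the list alone. The differentiation lists had medians of 0.36 (colonocyte, 11 members, adjusted p = 0.107, where the test leaned downwards; Krt20 0.43, SE 0.53, and Lypd8 0.52, SE 0.60) and 0.53 (goblet, 10 members, adjusted p = 0.398; Spink4 0.30, SE 0.73). S phase genes had a median of -0.13 (16 members, adjusted p = 0.132; Pcna -0.37, SE 0.19) and p53 targets 0.08 (6 members, adjusted p = 0.709; Cdkn1a 0.18, SE 0.34). Interferon genes had 0.27 (13 members, adjusted p = 0.562; Bst2 -0.23, SE 0.34) and MHC class I genes 0.05 (6 members, adjusted p = 0.664, test leaning downwards; B2m 0.04, SE 0.43). NF-kB and chemokine genes had 0.07 (15 members, adjusted p = 0.562, test leaning downwards; Cxcl2 -0.13, SE 0.81) and TGF-beta response genes -0.01 (13 members, adjusted p = 0.163; Id3 -0.32, SE 0.25). Unfolded protein response genes had 0.00 (11 members, adjusted p = 0.163, test leaning downwards; Hspa5 0.03, SE 0.16). Early genes of tissue dissociation had 0.14 (18 members, adjusted p = 0.415; Klf6 0.58, SE 0.22, unadjusted p = 0.0149, adjusted p = 0.949).

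**Figure D2:**
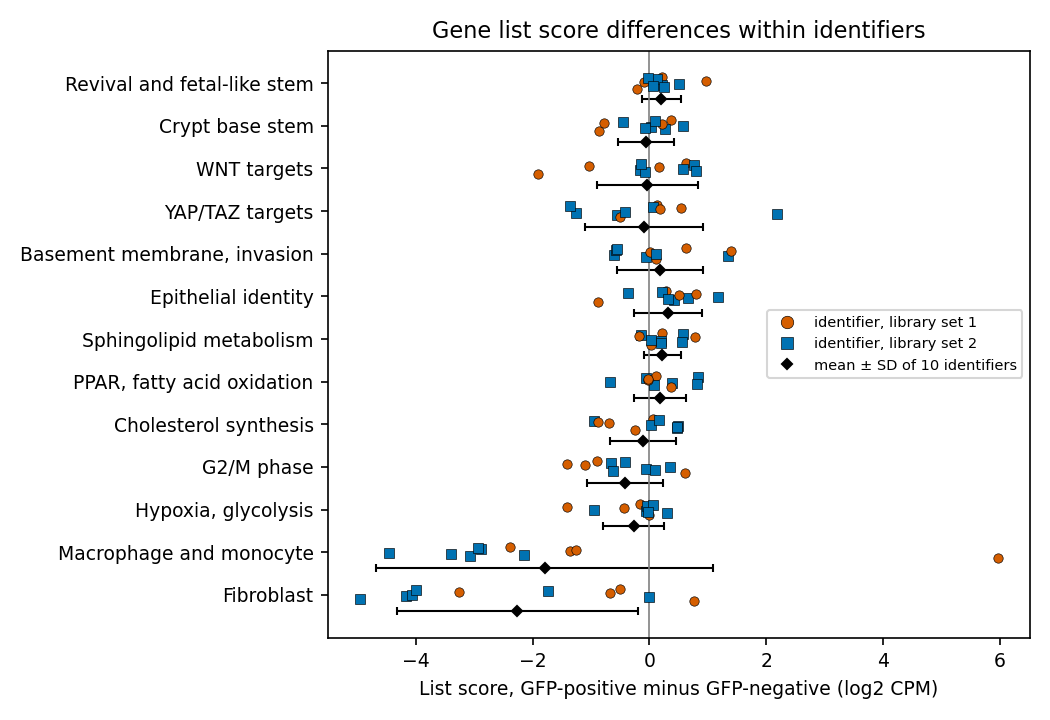
Difference in list score (mean log2 CPM of tested members), GFP-positive minus GFP-negative, for each of 10 identifiers, coloured by library set, with the mean ± SD as a diamond. Identifier 61-1, coloured as set 2, averages a GFP-positive library of each set. Fibroblast scores were lower in 9 of 10 identifiers, and macrophage scores in 9 of 10 with a difference of 5.96 in identifier 7789-7795.

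Scores of fibroblast and macrophage transcripts, cell types of the tumour stroma, were each lower in the GFP-positive population of 9 of 10 identifiers. All 6 tested fibroblast genes had a negative fold change, with a median of -2.20, and 5 were called lower adjusted over the list alone. The collagen genes Col1a1 and Col3a1 had -2.89 (SE 0.84, unadjusted p = 0.00233, edgeR adjusted p = 0.730) and -2.04 (SE 0.76, adjusted p = 0.949). The fibroblast list passed camera with its preset correlation (adjusted p = 8.84e-09), and not with an estimated correlation (adjusted p = 0.0669). The macrophage and monocyte list passed as lower (adjusted p = 1.21e-15, and 0.0669 with an estimated correlation), although its fitted median was 0.10 with 8 of 12 members positive. Its lysozyme gene Lyz2 had -0.06 (SE 0.95) and was lower in 9 of 10 identifiers, while Ptprc, the pan-leukocyte marker, had 0.05 (SE 0.89). With a block by identifier Lyz2 had -3.03 and Ptprc -1.17, neither called (edgeR adjusted p = 0.787 and 0.999), and C1qa and Apoe went from 0.27 and 0.49 to -3.24 and -3.07 (adjusted p = 0.903 and 0.790). This difference in sign came with GFP-positive 3, whose macrophage score was 10.5 against 3.53 to 5.91 in the other 10 GFP-positive libraries; without that library Apoe, C1qa, C1qb, Cd68, Fcer1g, Laptm5, Lyz2 and Tyrobp of this list were all called lower.

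Another 12 lists had fewer than 5 tested members and entered neither camera nor fry, although the scores of those with any tested member were compared. Fold changes of their most expressed members were -0.19 for Fn1 (SE 0.40, mesenchymal transition), 0.51 for Cpe (SE 0.32, enteroendocrine), 0.86 for Ptgs1 (SE 0.45, tuft) and 1.18 for Mptx1 (SE 1.23, Paneth). They were -0.50 for Ly6g (SE 0.28, neutrophil), 0.69 for Trbc1 (SE 0.36, T and NK cell), -0.54 for H2-Aa (SE 0.83, dendritic cell and MHC class II) and -1.31 for Acta2 (SE 0.67, smooth muscle and pericyte). The endothelial genes Flt1 and Pecam1 had -0.28 (SE 0.47) and -0.73 (SE 0.42), and the haemoglobin gene Hba-a2 had 0.11 (SE 0.62, erythrocyte). None of these genes passed the threshold (smallest adjusted p 0.996), and adjusted over the list alone 1 of the 3 tested mesenchymal genes was called lower. All 3 had a negative fold change, and the mesenchymal score was lower in 9 of 10 identifiers (exact sign-flip p = 0.0176, adjusted p = 0.290). Its differences ran with those of the fibroblast score. Both were positive in 7789-7795 alone (0.64 and 0.77), small in 7968 (-0.085 and -0.003) and large in 61-1 (-2.29 and -4.95). A change in tumour cells could therefore not be told from RNA of fibroblasts. The B and plasma cell list and the glia and neuron list had 0 tested members.

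Within library set 2, GFP-positive cells had far lower levels of macrophage and stromal matrix transcripts. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), an apolipoprotein abundant in macrophages, fell by 4.12 on the log2 scale (SE 0.34, edgeR adjusted p = 7.58e-08), from 781 ± 382 to 44.4 ± 24.2 CPM (SD, n = 6 and 6). C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), a complement chain made by macrophages, fell by 4.57 (SE 0.46, adjusted p = 6.41e-07), from 134 ± 37.8 to 5.84 ± 4.02 CPM (SD, n = 6 and 6). Ms4a6c and the integrin gene Itgam fell too, with log2 fold changes of -4.52 (SE 0.84) and -3.97 (SE 0.90). Of the macrophage list, 10 of 13 tested members were called lower (12 adjusted over the list alone), with a median of -3.66. Of the other genes named by the rule, Sfrp4 had a log2 fold change of -5.13 (SE 0.81). The matrix genes among them had -4.52 for Col15a1 (SE 0.62), -4.44 for Spon1 (SE 0.67), -4.30 for Eln (SE 0.83), -4.15 for Col6a3 (SE 0.59) and -4.02 for Col12a1 (SE 0.79). Each of these 10 genes was lower in 6 of 6 identifiers except Eln and Col12a1, which were lower in 5 of 6. Of the fibroblast list, 5 of 10 members were called lower (8 adjusted over the list alone), with a median of -2.93. The fixed list of basement membrane and invasion genes did not pass in this set (camera adjusted p = 0.211).

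Genes that rose in GFP-positive cells of library set 2 were fewer and changed less. Nupr1 (ENSMUSG00000030717), a stress-response nuclear protein, rose by 0.86 on the log2 scale (SE 0.20, edgeR adjusted p = 0.0209), from 2068 ± 211 to 3700 ± 1368 CPM (SD, n = 6 and 6). Tnfrsf11b (ENSMUSG00000063727), which encodes osteoprotegerin, rose by 1.29 (SE 0.31, adjusted p = 0.0281), from 158 ± 84.7 to 400 ± 57.7 CPM (SD, n = 6 and 6). Cdh13 (ENSMUSG00000031841), which encodes T-cadherin, rose by 1.16 (SE 0.28, adjusted p = 0.0314), from 167 ± 70.9 to 373 ± 104 CPM (SD, n = 6 and 6). All 3 were higher in 6 of 6 identifiers. In library set 1 Nupr1 had -0.14, Tnfrsf11b 0.12 and Cdh13 0.88, none called (edgeR adjusted p = 0.969, 0.985 and 0.933). Over both sets without joined identifiers, Tnfrsf11b and Cdh13 were called (1.245 and 1.29, edgeR adjusted p = 0.00417 and 0.00811). Nupr1 was not called there (0.64, adjusted p = 0.125). Over all libraries Cdh13 was called by DESeq2 (0.996, adjusted p = 0.0498), and by edgeR without GFP-positive 3 (1.14, adjusted p = 0.041). With macrophage and fibroblast scores as covariates over all libraries Nupr1, Tnfrsf11b and Cdh13 went from 0.46, 0.66 and 1.04 to 0.06, 0.15 and 0.75, uncalled by edgeR before and after (adjusted p = 0.990, 0.990 and 0.550 with covariates). In total 89 of 6952 tested genes were called in this set, 3 higher and 86 lower (478 at an unadjusted p under 0.05), and 63 of the 86 were lower in every identifier. A block by identifier gave 140 genes, 11 higher and 129 lower. With libraries of at least 100000 counts thinned to that depth, 24 genes were called, all lower, and Nupr1, Tnfrsf11b and Cdh13 had 0.71, 1.19 and 1.11 without a call (edgeR adjusted p = 0.205, 0.1003 and 0.0685).

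**Figure D3:**
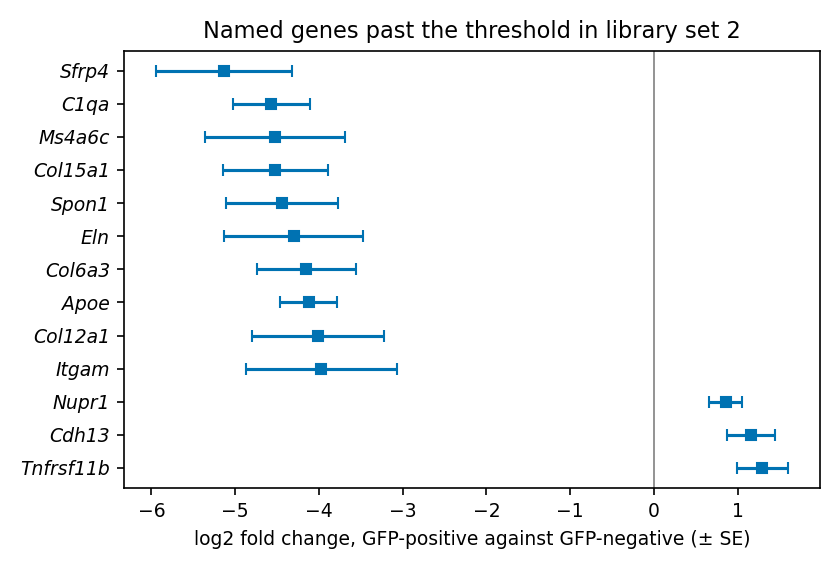
Log2 fold change (GFP-positive minus GFP-negative, ± SE) of the named genes past the threshold in library set 2 (n = 6 and 6). Sfrp4 and Apoe had values of -5.13 and -4.12, whereas Nupr1, Cdh13 and Tnfrsf11b had values of 0.86, 1.16 and 1.29.

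The macrophage and fibroblast lists were past camera in library set 2 with the preset correlation (adjusted p = 7.79e-35 and 1.40e-19) and with an estimated correlation (adjusted p = 0.00204 and 0.0168). Mesenchymal transition (median -1.10), TGF-beta response (-0.37), NF-kB and chemokine (-0.45) and dissociation genes (-0.28) passed as lower with the preset correlation alone (adjusted p = 8.38e-06, 0.00281, 0.00679 and 0.0142). With an estimated correlation their adjusted p was 0.104, 0.324, 0.580 and 0.580. Adjusted over the list alone, 2, 2, 0 and 0 of their members were called lower. Mesenchymal score differences ran with fibroblast ones over identifiers, so the mesenchymal list could not be told from RNA of fibroblasts. The revival list had a median of 0.32 over 21 members (adjusted p = 0.709) and the sphingolipid list 0.08 over 24 members (adjusted p = 0.915, with the test leaning downwards), neither past the threshold.

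In library set 1, no gene was called among 5256 tested (edgeR, 284 at an unadjusted p under 0.05, 127 higher and 157 lower; DESeq2 was not run within the set). Of the 89 genes called in library set 2, 32 were tested in library set 1, where 9 had the same sign and 23 the other. These signs rested on identifier 7789-7795: 20 of 32 had the same sign with a block by identifier, 20 of 23 without GFP-positive 3 and 10 of 11 without both libraries of 7789-7795. Without GFP-positive 3 edgeR called 1 gene in library set 1, Golm2, at -2.13 (SE 0.38, adjusted p = 0.0398). Without both libraries it called 14 of 2531 tested genes, 2 higher and 12 lower, and 0 of them were among the 89. Clu and Epcam rose, by 1.48 (SE 0.30, adjusted p = 0.0364) and 1.31 (SE 0.29, adjusted p = 0.0470) on the log2 scale, and the glycolysis genes Ldha and Pgk1 had -1.02 (SE 0.19, adjusted p = 0.0125) and -1.29 (SE 0.22, adjusted p = 0.00873; n = 5 and 4 libraries, genes chosen after their values were seen). Larger differences among the 14 included those of Ppp1r16b at -5.75, the keratin gene Krt15 at -3.86, Prr9 at -3.78 and Mt4 at -3.20. The GFP-negative libraries of this fit included GFP-negative 3, which carried hair keratin transcripts and the highest Prr9 level (801 CPM). They also included GFP-negative 4 and 5, with 57728 and 25458 counts and 32.1% and 12.0% mitochondrial ribosomal RNA. Over all 11 libraries of set 1, camera with its preset correlation passed 6 lists, lower for G2/M (median -1.12, adjusted p = 8.92e-07), cholesterol synthesis (-0.36, 0.000219), hypoxia and glycolysis (-0.52, 0.00138) and colonocyte genes (-0.05, 0.00927). It passed dissociation (median 0.63, adjusted p = 9.18e-05) and basement membrane genes (0.57, 0.0158) as higher. Adjusted over the list alone, 5 G2/M, 2 cholesterol, 3 hypoxia and 1 colonocyte genes were called lower, and 0 dissociation or basement membrane genes were called. With an estimated correlation none passed (adjusted p = 0.229, 0.229, 0.258, 0.493, 0.490 and 0.682 in the order given). The macrophage list did not pass over these 11 libraries (adjusted p = 0.561), with a fitted median of 1.57 against a test that leaned downwards.

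The difference between the library sets was tested itself, with identifier 61-1 counted in library set 2 although its GFP-positive value averaged GFP-positive 7 with GFP-positive 2 of library set 1. The interaction of group with library set called 0 of 6621 genes (edgeR, 424 at an unadjusted p under 0.05). DESeq2 called 11 of 23754, among them the macrophage genes Cd68 and Lyz2 and the collagen gene Col6a3. They also included the pancreatic enzyme gene Cela2a (-16.3), highest in the libraries of identifier 3034, and Prr9 (4.30), highest in GFP-negative 3. Macrophage scores within identifiers differed by -3.15 ± 0.76 in library set 2 (SD, n = 6) and by 0.24 ± 3.85 in library set 1 (SD, n = 4, exact permutation p = 0.00952, adjusted p = 0.236). Without identifier 7789-7795 the mean of library set 1 was -1.67 ± 0.63 (SD, n = 3, exact permutation p = 0.0238, adjusted p = 0.393), lower in 3 of 3 identifiers. Fibroblast scores differed by -3.15 ± 1.88 and -0.92 ± 1.69 (SD, n = 6 and 4, exact permutation p = 0.0762, adjusted p = 0.503). With pairs made within a library set, which leaves GFP-positive 2 out, the means of library set 2 were -3.16 ± 0.76 for macrophage and -3.09 ± 1.82 for fibroblast scores (SD, n = 6), and the exact permutation p stayed at 0.00952 and 0.0762 (adjusted p = 0.210 and 0.503). A difference in effect between the sets was therefore not established after adjustment by edgeR. The adjusted list scores could not decide it. With 210 splits, or 84 without identifier 7789-7795, and 33 lists, no single list could pass on its own.

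**Figure D4:**
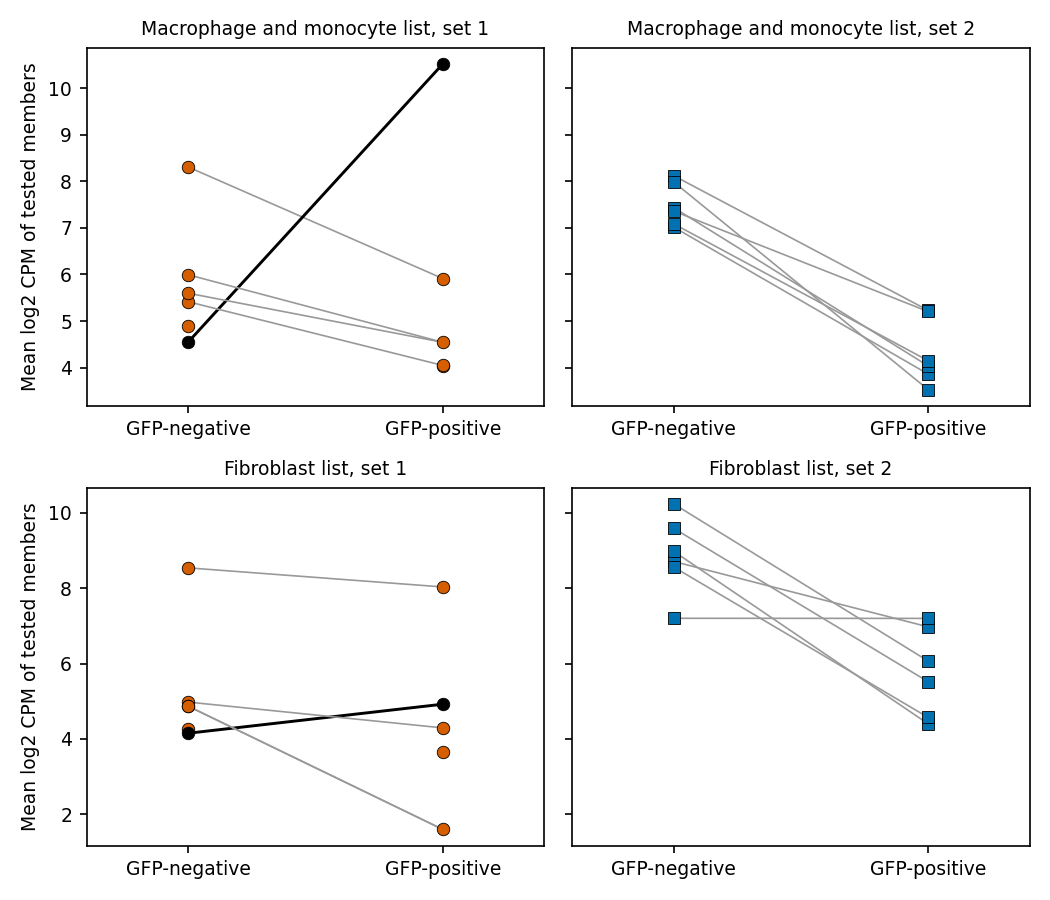
Mean log2 CPM of the macrophage (top) and fibroblast (bottom) lists in each library of set 1 (left) and set 2 (right); lines join libraries of an identifier, and identifier 7789-7795 is in black. Macrophage scores were lower in the GFP-positive library of 6 of 6 identifiers in set 2, and GFP-positive 3 stood at 10.5 in set 1.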

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

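Tests of depth, of further macrophage and fibroblast genes, of an exchange of libraries and of other splits of the samples were chosen after the results they bear on were seen, as were the comparisons without identifier 7789-7795 and with pairs made within a library set.

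Identifier 7789-7795 stood apart from the other 9 in 4 lists, and identifier 8045-8050 in 1, by the gap to the nearest value over the whole range. The macrophage score difference of 7789-7795 was 5.96 against -4.45 to -1.25 elsewhere (gap over range 0.692), and its dendritic cell and MHC class II difference was 5.84 against -3.21 to 0.14 (0.630). Its MHC class I difference was 1.85 against -0.66 to 0.65 (0.476), and its T and NK cell difference, carried by Trbc1 alone, was -1.29 against 0.14 to 1.76 (0.469). The unfolded protein response difference of 8045-8050 was -1.62 against -0.47 to 0.35 (0.584), and rests on libraries of 25458 to 57728 counts. All 5 exceed Dixon's 95% critical value for 10 values, and chance alone passes about 1 in 20 of the 33 lists examined.

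Score differences within identifiers also differed between the library sets for 3 of 33 lists before adjustment. For macrophage genes the exact permutation p was 0.00952, with means of -3.15 in library set 2 and 0.24 in library set 1. For dendritic cell and MHC class II genes it was 0.0143, with means of -2.85 and 0.39, and for S phase genes 0.0238, with means of 0.31 and -0.30. None passed Benjamini-Hochberg adjustment (adjusted p = 0.236, 0.236 and 0.262). With 210 splits, or 84 without identifier 7789-7795, no single list of 33 could pass on its own, so the adjustment decides little. The library set 2 value of identifier 61-1 averages in GFP-positive 2 of library set 1; with pairs made within a library set the exact permutation p was 0.00952, 0.0143 and 0.0190 (adjusted p = 0.210 for each). Without identifier 7789-7795 the p-values were 0.0238, 0.0357 and 0.0595 by the same exact permutation test, and 0.0357 for each with pairs made within a library set. G2/M genes, at 0.262 with all identifiers, then had an exact permutation p of 0.0238 (adjusted p = 0.393; means -0.22 in library set 2 and -1.14 in library set 1), and 0.0119 with pairs made within a library set (adjusted p = 0.295).

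The lower level of macrophage and fibroblast transcripts in GFP-positive libraries of set 2 was weighed against depth and RNA of other cells. Thinning the libraries of at least 100000 counts to 100000 left the median of 25 list members at -3.13 (quartiles -3.91 to -2.19, n = 5 and 6). It was -3.40 unthinned, so the difference held at equal read counts. Thinning keeps expected CPM ratios, so it cannot decide whether cell input or library complexity behind the depth played a part. Further lists, which share no gene with the fixed lists, had 23 tested members (12 of 20 macrophage and 11 of 18 fibroblast genes). All were lower, with medians of -2.994 for macrophage and -3.004 for fibroblast genes. A gene that passes the filter only through GFP-negative libraries can only be lower, so this share decides little. Sums over all members, tested or not, were lower in the GFP-positive library of each identifier of library set 2. For fibroblast genes the sum fell only from 1426 to 1116 CPM in 5780 and from 1207 to 904 CPM in 7968. The pattern may come from RNA of macrophages and fibroblasts in the GFP-negative libraries. In that case part of the contrast may reflect host cells, since the labels name no gate other than GFP. Expression of these genes by GFP-negative tumour cells stays open, because how many of them tumour cells also express was not measured here.

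GFP-positive 3 had a macrophage score of 10.5, above the other GFP-positive libraries (4.46 ± 0.75, SD, n = 10) and above every GFP-negative library. Of 20 further macrophage genes, 90% had their highest CPM of all libraries there, such as Ctsc at 1004 CPM and Fcgr2b at 694 CPM, so RNA of macrophages in that library may be its source, although a GFP gate would remove macrophages that lack the reporter. An exchange of both libraries of 7789-7795 cannot be told apart from it: GFP-negative 6 scored 4.55, under the other GFP-negative libraries (4.90 to 8.30) by less than their SD of 1.18. Basp1 ran as labelled in this pair (75.6 against 60.3 CPM, a log2 difference of 0.32), which does not settle it beside an SD of 0.95 over the 9 identifiers other than 8045-8050. No biological explanation was tested, since the design names none for 1 library.

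Other splits of the libraries into groups of the same sizes tested whether chance can be excluded. For all 23 libraries, 4 of 100 splits called as many genes (real 1, highest other 1). A count of 1 gene, which other splits reached too, cannot decide the question. At an unadjusted p under 0.05, 13 of 100 splits had at least the real 328 genes (highest other 685), so chance is not excluded. With the preset correlation 30 of 100 passed as many lists (real 5, highest other 11), so chance is not excluded there either. In library set 2, 1 of 100 splits called as many genes (real 89, highest other 39). As many lists passed with an estimated correlation in 1 of 100 (real 2, highest other 1). No other split reached either count, so chance is unlikely for the 89 genes, though 100 splits do not exclude it. For lists, 5 other splits passed any, and 2 against 1 is too small a gap to decide. The splits redrew libraries freely and did not keep the libraries of an identifier paired. With the preset correlation 32 of 100 passed as many lists in library set 2 (real 6, highest other 14) and 11 of 100 in library set 1 (real 6, highest other 10), so chance is not excluded. In library set 1 all 100 splits called at least the real 0 genes (highest other 23), and all 60 redrawn labellings at least the real 0 with an interaction (highest other 2), as any split must, so these counts exclude nothing. The split with 23 calls may point to a structure of the samples other than GFP, which was not identified.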

How the results depend on the processing

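Blocks, scalings, filters, tools, single library sets and omissions were fixed beforehand; fits on deep, thinned or quality-weighted libraries, without GFP-positive 3 under a block or at depth, with macrophage and fibroblast covariates, with an estimated correlation in single alternatives, and sign-flip tests of list scores were chosen after the result was seen. Basp1 kept a positive log2 fold change between 0.36 and 0.81 and was called in none of the fits that tested it. Fbln1 was lower in all 38 alternatives that tested it (log2 fold change -3.80 to -2.50, adjusted p 2.00e-06 to 0.116) and passed the threshold in 35. The number of genes called moved most, between 0 and 140. Leaving out the 4 libraries under 100000 counts left the number called at 1, and with libraries thinned to 100000 counts 1611 genes could be tested. At the depth and number of all libraries, 51.5% of genes changed by 2-fold were called in simulated data. That simulation changed 200 genes, which eases the Benjamini-Hochberg threshold, whereas the real fit called 1. The real share may thus be lower, and changes of that size can be missed. Unless an alternative tested fewer genes or libraries, the cause was not tested.

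The count of genes called over all libraries was 1 (0 higher, 1 lower). DESeq2 gave 61 (2 higher, 59 lower). A filter of at least 10 counts in 11 libraries gave 0 (0 lower; 325 at an unadjusted p under 0.05). Library set 1 gave 0 (0 lower) and library set 2 gave 89 (3 higher, 86 lower). Leaving out libraries with joined identifiers gave 30 (4 higher, 26 lower). Macrophage and fibroblast covariates gave 2 (2 lower). Leaving out GFP-positive 3 and libraries under 100000 counts gave 0 (0 lower; 451 at an unadjusted p under 0.05). Thinning all deep libraries gave 0 (0 lower; 101 at an unadjusted p under 0.05), and thinning those of library set 2 gave 24 (24 lower). Leaving out each library gave 0 to 16 genes (0 to 1 higher, 0 to 15 lower), with 16 without GFP-positive 3, 3 without GFP-positive 1 and 0 without any of GFP-negative 1, 2 and 5 to 12. Leaving out each identifier gave 0 to 27 genes (0 to 2 higher, 0 to 25 lower), with 27 without 7789-7795. The interaction with library set gave 0 by edgeR and 11 by DESeq2 (424 of 6621 and 859 of 23754 tested genes at an unadjusted p under 0.05).

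Whether the identifier pairs the libraries was not settled. Of 11 GFP-positive libraries, 4 correlated best, among all 12 GFP-negative libraries, with a library of their own identifier. The correlation with it was over 0.1 in 5 of 11, and its median was 0.082, against -0.018 for the same title number. How many best matches chance would give was not tested. A block by identifier gave 3 genes (3 lower: Fbln1, Fndc1 and Igfbp3), a block by title number 2 (2 lower), a block in library set 1 gave 0 (0 lower) and a block in library set 2 gave 140 (11 higher, 129 lower). A block without GFP-positive 3 gave 100 genes (13 higher, 87 lower) and 8 lists, and the same block without libraries under 100000 counts gave 92 (7 higher, 85 lower). A block in deep libraries gave 8 lists. Under a block, the adjusted p of the cholesterol list was 0.888 in library set 2, 0.180 in deep libraries, 0.111 without GFP-positive 3 and 0.328 without it in deep libraries. That of the hypoxia list was 0.0923 in library set 2 and 0.0680 without GFP-positive 3 in deep libraries, that of the G2/M list 0.106 in library set 2, and that of the macrophage list 0.852 in library set 1. A block moved no other value of these lists across the threshold.

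Lists past camera numbered 5, against 10 with no filter, 8 without joined identifiers and 8 with covariates. They numbered 0 with thinned libraries and 3 with thinned libraries of set 2. With an estimated correlation, with fry or with sign-flip tests the number was 0. Sign-flip tests over 10 identifiers and 33 lists could not pass a single list on its own. Leaving out a library gave 5 to 8 lists (8 without GFP-positive 6). Some lists uncalled over all libraries gained a call in alternatives, among them colonocyte genes in 14, TGF-beta response genes in 11 and epithelial identity genes in 6. These counts rest on the preset correlation. With an estimated correlation the adjusted p was 0.446 (cholesterol), 0.0535 (G2/M), 0.0669 (hypoxia), 0.0669 (macrophage) and 0.0669 (fibroblast), and with fry 0.839, 0.240, 0.397, 0.240 and 0.240. In library set 2 it was 0.903 (cholesterol), 0.113 (G2/M) and 0.0856 (hypoxia), in library set 1 0.561 (macrophage), with covariates 0.104 (fibroblast), with thinned libraries 0.979 (cholesterol) and 0.0668 (hypoxia), and with thinned libraries of set 2 0.504 (hypoxia).

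C1qa, Ms4a6c and Apoe had positive fitted values over all libraries. With all libraries kept they turned negative without a call under a block by identifier (-3.24, -3.28 and -3.07), a block by title number (-2.91, -2.71 and -2.87), a block as a random effect (-2.12, -2.23 and -1.91), library set as a covariate (-1.23, -0.87 and -1.16), quality weights (-2.73, -2.56 and -2.45) and macrophage and fibroblast covariates (-0.40, -0.76 and -0.52). They were called lower in the following fits. Their log2 fold changes were -2.80, -3.33 and -2.88 by DESeq2, -4.57, -4.52 and -4.12 in library set 2, -4.64, -4.55 and -4.10 with a block there, and -3.39, -3.74 and -3.22 without joined identifiers. They were -3.19, -3.61 and -3.11 without GFP-positive 3, -3.34, -3.76 and -3.24 without identifier 7789-7795, -3.75, -3.91 and -3.48 with a block and without GFP-positive 3, and -3.84, -3.67 and -3.52 when shallow libraries were left out too. Apoe had -4.98 in thinned libraries of set 2. Leaving out each library or identifier in turn, C1qa ran from -3.34 to 0.80, Ms4a6c from -3.76 to 0.95 and Apoe from -3.24 to 0.97. The dissociation list leaned higher over all libraries and was called lower in library set 2 (adjusted p = 0.0142), with a block there (0.0106), with a block in deep libraries (0.0398), with that block without GFP-positive 3 (0.00405) and in thinned libraries of set 2 (0.00736). The NF-kB list was called higher with covariates (0.0374), and the basement membrane list lower in thinned libraries of set 2 (0.0458). With an estimated correlation none of these calls held: the adjusted p of the dissociation list was 0.580, 0.775, 0.786, 0.511 and 0.553 in the order given, that of the NF-kB list 0.567 and that of the basement membrane list 0.553. The cause was not tested.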

Other observations

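The gene sets of mucus, hair keratin and pancreatic enzyme genes were chosen after their levels were seen, as was the test of carry-over; the further acinar list and the adipocyte list were written before their levels were looked up.

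Genes of normal colon mucosa, among them Mptx1, Zg16, Clca1 and Tff3, summed to 10655 CPM in GFP-positive 7 and 11058 CPM in GFP-positive 8, and to 3817 and 4585 CPM in the GFP-negative libraries of the same identifiers (GFP-negative 8 and 9); of these 4, all but GFP-negative 8 carry the name suffix -2. The other GFP-positive library of identifier 61-1, GFP-positive 2 of library set 1, had 112 CPM for the same 8 genes, of which 5 are also in a fixed list. Within library set 2 all 8 genes had a positive fold change, with a median of 0.98, and 0 were called by edgeR. Their sum was higher in the GFP-positive library of 3 of 6 identifiers, and the genes were picked for their level in GFP-positive 7 and 8. Hair keratin genes such as Krt34, Krt33a and Krtap3-1 summed to 3241 CPM in GFP-negative 3, and to at most 353 CPM in any other library.

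Besides macrophage and fibroblast genes, the calls in library set 2 included antigen presentation genes of MHC class II. Cd74, the invariant chain, fell by 3.48 on the log2 scale, and H2-Ab1, H2-Aa and H2-Eb1 had log2 fold changes of -2.89, -2.88 and -2.56, all chosen after their values were seen. The membrane-bound metalloproteinase gene Mmp14 had -3.46, Igfbp3 -2.55 and the fibronectin gene Fn1 -0.97. Of the 89 genes called, 15 belonged to the macrophage and fibroblast lists and 7 to any other fixed list.

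Pancreatic digestive enzyme transcripts were abundant in both libraries of identifier 3034: 13 genes took 2.04% of the counts in GFP-negative 1 and 1.00% in GFP-positive 1, with Amy2a3, a pancreatic amylase, at 8650 and 4726 CPM. Of 11 detected genes of a further acinar list, none of them in a fixed list, 81.8% had their 2 highest values in these libraries, such as Cel at 433 and 168 CPM, consistent with pancreatic acinar cells in the sorted material. Carry-over of reads between the libraries is argued against, since GFP-positive 1 held 4.90 times the enzyme counts of GFP-negative 1 at 0.491 times the CPM. Adipose tissue in the material as well was neither shown nor excluded, since 63.6% of 11 detected adipocyte genes were highest in a library of 3034. A sort on GFP names no gate that would remove such cells from the GFP-negative population, whereas it would remove acinar cells without the reporter from GFP-positive 1, and no biological explanation was tested.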
